A study of Mus musculus with 15 samples.

How the data were processed

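Tregs were sorted from untreated skin, MC903-treated skin and skin-draining lymph nodes, and their RNA was made into libraries with a SMART-Seq v4 kit and read as 75 bp single-end reads on an Illumina NextSeq instrument, per the labels' protocols. The 15 libraries were put into 5 groups of 3 from their titles. Reads were aligned with TopHat2 2.0.6 to mm9 and compared with DESeq2, for which no version is given, per the submitters' processing notes. How reads were assigned to genes, and with which annotation, is not recorded, so reads shared by near-identical genes, such as Hmga2-ps1 or members of a gene family, and by overlapping genes may be split in an unknown way.

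The authors deposited a table of raw counts per gene and library, which are whole numbers, and a table of their LN against skin comparison. Per the file headers, the latter holds a mean normalised signal, a log2 fold change with its standard error, a score that is the fold change over that error, a p-value and an adjusted p-value. Whether the authors' log2 fold changes are shrunken is not stated. The main comparisons were computed from the deposited counts alone. Total counts ran from 19.8 to 27.7 M per library, M being the usual mega prefix. PCR reads without molecular identifiers are not independent molecules.

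Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr over the 5 groups, which left 13578 of 24015. Libraries were scaled by TMM (factors 0.903 to 1.26), 1 model was fitted to all 15 libraries, and each contrast was tested by the robust quasi-likelihood F test with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05. The common dispersion was 0.138, a biological coefficient of variation of 37.2%. The comparisons were WT skin against LN, cKO against WT in each treatment, MC903 against untreated in each genotype, the genotype by MC903 interaction and the genotype effect averaged over treatments. CPM are counts per M of the TMM-scaled library size. Replicate numbers in the titles were checked and did not pair libraries across groups.

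Before the data were examined, 27 gene lists were written, and 26 had the 5 tested members needed for camera, run with a preset correlation of 0.01 and again with an estimated correlation, two-sided, adjusted over the lists of a comparison. The lists were Treg identity, tissue Treg programme, lymphoid and resting T cell programme, T cell migration and skin homing receptors, type 2, type 17 and type 1 programmes, TNF receptor superfamily and ligands, suppressive molecules, NF-kappa-B targets, TCR activation, immediate early and heat shock genes, interferon-stimulated genes, cell cycle, circadian clock and ROR or REV-ERB targets, glycolysis and hypoxia, oxidative phosphorylation, lipid uptake and oxidation, cholesterol synthesis and vitamin D response. Markers of other cells made up lists for keratinocytes, fibroblasts and endothelium, macrophages, dendritic and Langerhans cells, B cells, mast cells, basophils and granulocytes, CD8, gamma-delta T, NK and innate lymphoid cells, and erythroid cells and platelets.

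Genes to name were also fixed by rule beforehand. Among the genes followed throughout were Rora, Foxp3, Tnfrsf25, Il4, Il5, Il13, Il10, Areg, Il1rl1 and Gata3. In the first 4 comparisons and the averaged genotype effect the rule takes the 8 called genes with the largest change in each direction, at a mean log2 CPM of 3 or more and with the groups' libraries apart. In the other comparisons it takes the 3 called genes with the smallest adjusted p in each direction. It adds up to 4 called members of each list with the smallest adjusted p, or the 1 with the smallest p, and leaves out unnamed gene models. Of the called genes so taken, the text describes mainly those whose call held under every alternative, a choice made after the alternatives were run. These were 102 of 116 for skin against LN, 15 of 30 for genotype in untreated skin, 8 of 20 for genotype in MC903 skin, 31 of 37 for the averaged genotype effect, and 51 of 74 for MC903 in each genotype.

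Alternatives were DESeq2's Wald test, relative log expression factors, no filter beyond 1 count, a filter of 50 counts in 3 libraries, only the compared groups in the fit, the replicate number as a block, limma-voom with sample weights, and each library left out in turn. Added after seeing the data were runs without the 3 libraries with the most fibroblast and endothelial transcripts, without replicate 3 of LN and replicate 2 of WT untreated skin together, and without the genes of 2 chromosome segments. The pipeline was tested on simulated data with 200 changed genes among 13578, none of them from the lowest expressed. The oxidative phosphorylation list was raised as well. Counts were drawn for each gene on its own, so transcripts of other cells shared within a library were not simulated. The rates may be better than in the real libraries. For the genotype comparison in untreated skin it recovered 48.0% of changes of 1 and 82.0% of changes of 2 on the log2 scale, with 1.36% of calls false. For the averaged genotype effect it recovered 75.0% and 97.0%, with 7.73% false. Neighbouring genes were found by symbol in a RefSeq table of another build, GRCm38.p6, which matched 13524 of the genes tested and was used only for the order of genes and the distances between them.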

Results

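RNA was sequenced from regulatory T cells (Tregs) of C57BL/6 mice in which Foxp3, the gene of the lineage-defining transcription factor, drives Cre and a yellow fluorescent protein (YFP). The cells were sorted as CD45+CD3+CD4+YFP+. The 15 libraries form 5 groups of 3. Wild-type (WT) Tregs came from untreated skin, from skin treated with MC903 and from skin-draining lymph nodes (LN). Tregs that also carry floxed Rora alleles, here called cKO, came from untreated skin and from MC903-treated skin. MC903 (calcipotriol) is a vitamin D analogue that inflames skin, and it was put on the ears 4 times. Untreated skin was back skin with ears and treated skin was ears alone, so the site sampled moved with the treatment. Skin was digested for 90 minutes and LN were homogenised without a stated digestion, so the digestion moved with the tissue.

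The authors' deposited table of counts holds 24015 genes. Total counts were 22.9, 25.1 and 19.8 M for WT untreated skin, 25.1, 24.5 and 27.2 for cKO untreated skin, 26.96, 25.98 and 25.9 for WT MC903 skin, 24.5, 21.03 and 21.4 for cKO MC903 skin and 24.6, 27.7 and 25.3 for LN. After the filter on low counts, 13578 genes were tested. The first principal component held 51.3% of the variance and set the 3 LN libraries apart from the 12 skin libraries, and the second held 11.6%. The p-values below measure only the spread between these samples.

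Rora, the floxed gene, encodes the nuclear receptor ROR-alpha. It was read at 1327, 1341 and 1510 counts scaled to library size (CPM) in the WT untreated skin libraries and at 822, 1074 and 1199 CPM in the cKO ones. In MC903 skin it was read at 813, 739 and 812 CPM in WT and 632, 492 and 473 CPM in cKO. LN Tregs held 58.6, 52.8 and 66.6 CPM. Each cKO library lay below each WT library of the same treatment. The log2 difference was -0.43 ± 0.15 in untreated skin (SE, adjusted p = 0.25) and -0.57 ± 0.15 in MC903 skin (adjusted p = 0.191), and neither passed the test. Averaged over both treatments Rora fell, by a log2 change of -0.50 ± 0.10 (adjusted p = 0.0193). That call ended without replicate 3 of WT untreated skin (adjusted p = 0.0532), replicate 1 of WT MC903 skin (0.0629), or replicate 2 or 3 of cKO MC903 skin (0.0634 and 0.0671). An allele that lacks an exon can still give transcripts, and a count per gene does not show which exons the reads came from.

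**Figure D1:**
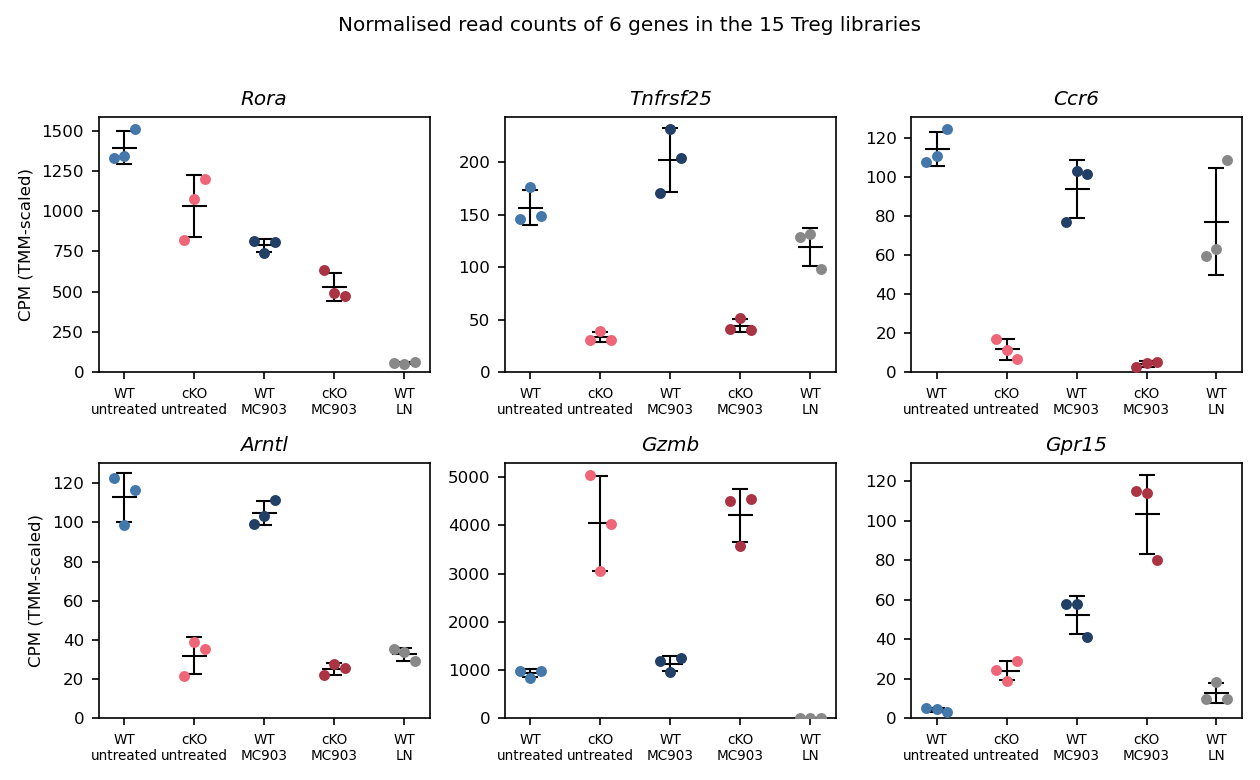
Scaled counts (CPM) of 6 genes in each of the 15 libraries, by group, with the mean and SD of each group. Rora lies at 1393 ± 102 CPM (SD) in WT untreated skin, 1031 ± 192 in cKO untreated skin and 59.3 ± 6.92 in LN.

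Skin and LN Tregs of WT mice were compared to find what marks the skin-resident cells. Skin Tregs held far more transcript of the cytokine gene Il10 (log2 change 7.63 ± 0.21, SE, n = 3 per group), of the cytotoxic protease gene Gzmb (6.40 ± 0.29), of the tissue repair factor gene Areg (6.20 ± 0.27) and of Il1rl1, the receptor of interleukin 33 (4.88 ± 0.18). Rora itself was higher by 4.55 ± 0.17. LN Tregs held more of the follicle homing receptor gene Cxcr5 (-8.40 ± 0.50), the survival gene Bcl2 (-6.05 ± 0.27) and the transcription factor gene Lef1 (-3.56 ± 0.18). Foxp3 was higher in skin by 2.57 ± 0.26. Among the genes that moved most were Calca, which encodes a neuropeptide precursor (9.89 ± 0.44), and the stress transcription factor gene Atf3 (10.17 ± 0.39) on the skin side, and the ATP receptor gene P2rx7 (-7.12 ± 0.79) on the LN side. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3911 genes were higher in skin and 3913 were lower.

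All 25 tested genes of the tissue Treg programme rose in skin, and all 25 did so adjusted over the list alone (camera adjusted p = 3.51e-49, adjusted p = 4.42e-05 with an estimated correlation). They include Dgat1, which makes triglycerides (5.12 ± 0.12). Among the 18 lymphoid and resting T cell genes, 2 rose, 12 fell and 4 did not pass the test (2 rose and 12 fell adjusted over the list alone). By camera, lymphoid and resting genes had adjusted p = 2.21e-06, and adjusted p = 0.0089 with an estimated correlation. In the type 2 list of 20 genes, which holds Areg and the transcription factor gene Gata3 (1.51 ± 0.13), 15 rose, 1 fell and 4 did not pass the test (15 rose and 1 fell adjusted over the list alone). By camera, the type 2 list had adjusted p = 3.27e-07, and adjusted p = 0.00395 with an estimated correlation. Among the 20 suppressive molecules, which include the inhibitory receptor gene Ctla4 (3.52 ± 0.15), 12 rose, 0 fell and 8 did not pass the test (12 rose and 1 fell adjusted over the list alone). By camera, suppressive molecules had adjusted p = 2.05e-11, and adjusted p = 0.0215 with an estimated correlation. NF-kappa-B targets such as Gadd45b (5.49 ± 0.15) and Tnfaip3 (4.41 ± 0.23) rose in skin: of 20, 18 rose, 0 fell and 2 did not pass the test (19 rose and 0 fell adjusted over the list alone). By camera, NF-kappa-B targets had adjusted p = 2.85e-21, and adjusted p = 1.77e-04 with an estimated correlation. All 25 immediate early and heat shock genes, written down beforehand as a sign of tissue digestion, rose in skin, with Dusp1 at 5.05 ± 0.22 and Junb at 4.44 ± 0.22 (25 rose adjusted over the list alone, camera adjusted p = 1.55e-30, adjusted p = 0.0027 with an estimated correlation). In the list of 23 circadian clock genes and targets of the ROR and REV-ERB receptors, 15 rose, 0 fell and 8 did not pass the test (15 rose and 0 fell adjusted over the list alone). By camera, the clock list had adjusted p = 3.06e-06, and adjusted p = 0.0306 with an estimated correlation. Nr1d1, which encodes REV-ERB-alpha, was at 4.27 ± 0.33.

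The next lists passed camera at the preset correlation and not with an estimated one. Of 18 Treg identity genes, 12 rose, 3 fell and 3 did not pass the test (12 rose and 3 fell adjusted over the list alone), and Nrp1 was among those that fell (-2.59 ± 0.17). By camera, Treg identity had adjusted p = 0.00311, and adjusted p = 0.0573 with an estimated correlation. Migration and skin homing receptors such as Cxcr6 (4.37 ± 0.24) and Ccr2 (3.56 ± 0.25) had 20 members tested: 11 rose, 6 fell and 3 did not pass the test (11 rose and 6 fell adjusted over the list alone). By camera, homing receptors had adjusted p = 0.00136, and adjusted p = 0.178 with an estimated correlation. Of 18 type 17 genes, 10 rose, 0 fell and 8 did not pass the test (10 rose and 0 fell adjusted over the list alone). By camera, type 17 genes had adjusted p = 0.00196, and adjusted p = 0.15 with an estimated correlation. TCR activation genes, led by Nr4a2 (5.30 ± 0.28), gave this count of 20: 10 rose, 3 fell and 7 did not pass the test (10 rose and 4 fell adjusted over the list alone). By camera, TCR activation genes had adjusted p = 0.031, and adjusted p = 0.3 with an estimated correlation. The interferon-stimulated list went down, with Usp18 at -5.24 ± 0.42 and Ifit2 at -4.19 ± 0.29. Of its 24 genes, 1 rose, 21 fell and 2 did not pass the test (1 rose and 22 fell adjusted over the list alone). By camera, interferon-stimulated genes had adjusted p = 3.06e-06, and adjusted p = 0.183 with an estimated correlation. Of 28 cell cycle genes, 1 rose, 16 fell and 11 did not pass the test (1 rose and 16 fell adjusted over the list alone). By camera, cell cycle had adjusted p = 0.031, and adjusted p = 0.654 with an estimated correlation, and the mitotic kinase gene Plk1 was at -3.71 ± 0.51. Glycolysis and hypoxia genes went up, with the oxygen sensor gene Egln3 at 4.83 ± 0.16. Of 24, 20 rose, 2 fell and 2 did not pass the test (20 rose and 2 fell adjusted over the list alone). By camera, glycolysis and hypoxia had adjusted p = 5.20e-07, and adjusted p = 0.0686 with an estimated correlation. Of 27 lipid uptake and oxidation genes, 12 rose, 7 fell and 8 did not pass the test (12 rose and 7 fell adjusted over the list alone). By camera, lipid uptake and oxidation had adjusted p = 0.00997, and adjusted p = 0.15 with an estimated correlation, and Dgat2 was at 5.93 ± 0.24.

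Lists of other cell types moved too. Keratinocyte markers summed to 498 ± 186 CPM (SD, n = 3) in WT untreated skin and 18.9 ± 0.940 CPM in LN. Of 16 tested, 11 rose, 1 fell and 4 did not pass the test (11 rose and 1 fell adjusted over the list alone). By camera, keratinocyte markers had adjusted p = 0.00464, and adjusted p = 0.393 with an estimated correlation, and Sfn was at 5.09 ± 0.20. B cell markers summed to 10.7 ± 2.52 CPM in skin and 516 ± 406 CPM in LN, where replicate 3 held 984 CPM. All 13 fell in skin, also adjusted over the list alone (camera adjusted p = 2.63e-05, adjusted p = 0.17 with an estimated correlation), with Cd79a at -6.68 ± 0.57. The other lists did not pass camera (adjusted p = 0.132 to 0.534). They are the type 1 list (7 of 16 rose and 2 fell), TNF receptors and ligands (10 of 33 rose and 13 fell, median 0.18 and mean -0.16), oxidative phosphorylation (3 of 32 rose and 8 fell), cholesterol synthesis (8 of 24 rose and 3 fell) and vitamin D response (5 of 9 rose and 1 fell). The same held for fibroblast and endothelial markers (10 of 17 rose and 1 fell), macrophage, dendritic and Langerhans cell markers (6 of 21 rose), mast cell, basophil and granulocyte markers (4 of 14 rose and 1 fell) and CD8, gamma-delta T, NK and innate lymphoid markers (1 of 11 rose and 4 fell). Adjusted over each list alone, 7 and 2, 10 and 14, 3 and 8, 8 and 3, 5 and 1, 10 and 1, 5 and 0, 4 and 1, and 0 and 3 rose and fell, in the same order. The erythroid and platelet list had 3 tested members, too few for the set test.

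**Figure D2:**
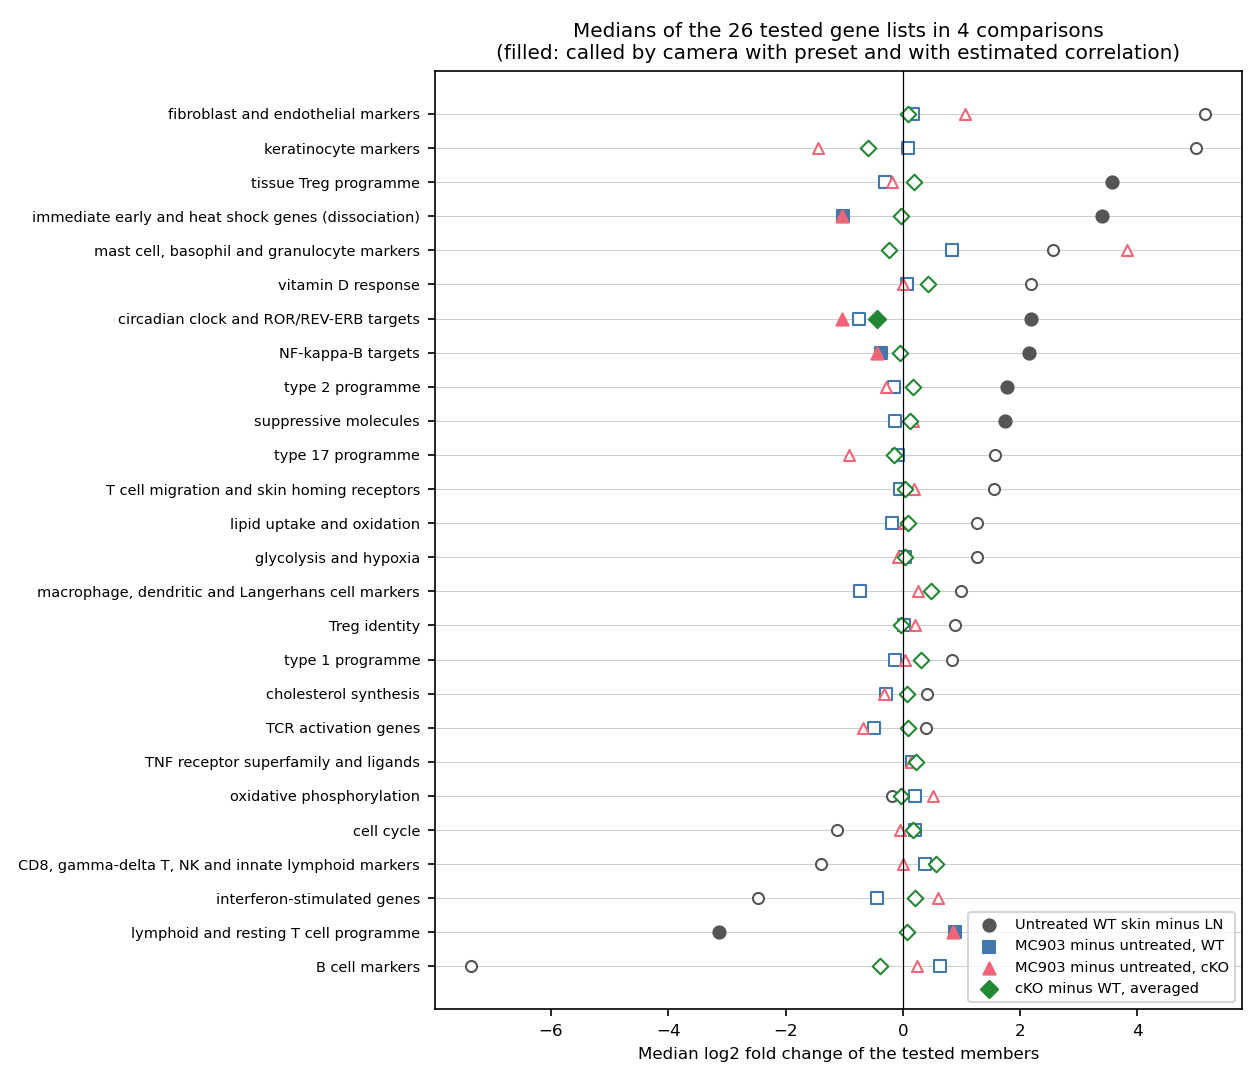
Median log2 fold change of each gene list in 4 comparisons, with filled marks for lists that passed camera both at the preset correlation and with an estimated correlation. The tissue Treg programme stands at a median of 3.56 in skin over LN, and the clock list at -0.45 in the averaged genotype effect.

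The authors' deposited table of the same skin and LN comparison was set beside this fit. The authors' deposited table calls 7929 genes at an adjusted p under 0.05, 3880 higher in LN and 4049 higher in skin. Of these, 7889 were tested in the edgeR fit, and 94.7% of them passed there in the same direction. The log2 fold changes of the authors' deposited table and of the fit correlated across genes at r = 0.854, with a slope of 0.543 for the deposited values on those of the fit. The deposited change of Krt14 was -1.68 ± 0.75 (LN minus skin, SE). Krt14 held 52.2 ± 43.5 CPM (SD) in WT untreated skin and 0.0105 ± 0.0181 CPM in LN. That deposited value is far smaller than the counts give, as a shrunken one would be. Genes are not independent replicates.

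In untreated skin, cKO Tregs were compared with WT Tregs to find what differs with genotype. The genes that fell most were Colq, which encodes the collagen tail of acetylcholinesterase (log2 change -4.70 ± 0.38, SE, n = 3 per group, adjusted p = 9.11e-06), and the chemokine receptor gene Ccr6 (-3.27 ± 0.34). Tnfrsf25, a receptor of the TNF receptor family, fell from 157 ± 16.9 CPM (SD) to 33.8 ± 4.60 CPM, a log2 change of -2.21 ± 0.17. Nr1d1 (-1.94 ± 0.30), the clock activator gene Arntl (-1.82 ± 0.19) and the water and glycerol channel gene Aqp3 (-1.56 ± 0.25) fell as well. Among the genes that rose were the phosphodiesterase gene Pde3b (3.29 ± 0.34), the glutamate decarboxylase gene Gad1 (2.95 ± 0.36), Gzmb (2.11 ± 0.23, from 934 ± 80.5 to 4039 ± 988 CPM) and the nucleotide sugar receptor gene P2ry14 (1.95 ± 0.29).

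In this comparison 54 genes were higher and 55 lower in cKO. In all 109 of them the libraries of one group lay above those of the other. Of all genes tested 13.6% were split so, and chance gives 10%. The calls and the split use the same values, so the split is no separate support for the calls. Nt5e, which encodes the adenosine-producing enzyme CD73, fell by 2.66 on the log2 scale, and Mns1 fell by 2.37. Both lie within 20 Mb of Rora on chromosome 9. Of 33 TNF receptors and ligands, 3 rose, 2 fell and 28 did not pass the test (8 rose and 2 fell adjusted over the list alone). By camera, TNF receptors and ligands had adjusted p = 0.0777, and adjusted p = 0.471 with an estimated correlation. Tnfsf8, the CD30 ligand gene (2.13 ± 0.30), and Cd40lg, the CD40 ligand gene (1.18 ± 0.16), were among those that rose. The circadian clock list passed camera, downward: of 23, 0 rose, 2 fell and 21 did not pass the test (0 rose and 6 fell adjusted over the list alone). By camera, the clock list had adjusted p = 3.13e-04, and adjusted p = 0.442 with an estimated correlation. Oxidative phosphorylation genes also passed downward at a median of -0.19: of 32, 0 rose, 1 fell and 31 did not pass the test (0 rose and 1 fell adjusted over the list alone). By camera, oxidative phosphorylation had adjusted p = 1.78e-04, and adjusted p = 0.869 with an estimated correlation. The other lists did not pass (adjusted p = 0.0777 to 0.94). Gata3 passed at 0.59 ± 0.13 (adjusted p = 0.0448), but not without replicate 2 or 3 of WT skin or any 1 of the 3 cKO libraries (adjusted p = 0.0575 to 0.173). Markers of CD8, gamma-delta T, NK and innate lymphoid cells summed to 18.8 ± 0.721 CPM in WT and 33.3 ± 3.80 CPM in cKO, and keratinocyte markers to 498 ± 186 and 372 ± 112 CPM. The number of genes called was 60 without replicate 3 of WT skin, 67 without replicate 2 of cKO skin, 62 without replicate 3 of cKO skin, and 323 by DESeq2. With only these 6 libraries in the fit 53 were higher and 26 lower, and without replicate 2 of WT skin 33 were higher and 54 lower. Without the 3 libraries richest in fibroblast and endothelial transcripts, a choice made after seeing the data, 54 genes were called.

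In MC903-treated skin the same genotypes were compared to see what differs with genotype in inflamed skin. Ccr6 (log2 change -4.47 ± 0.36, SE, n = 3 per group, adjusted p = 2.14e-05), Colq (-3.74 ± 0.36), Tnfrsf25 (-2.19 ± 0.16), Arntl (-2.05 ± 0.19) and Aqp3 (-1.87 ± 0.25) fell here too. The clock repressor gene Cry1 fell (-1.50 ± 0.16, from 168 ± 17.6 to 59.5 ± 9.09 CPM, SD). Gzmb rose (1.90 ± 0.23, from 1130 ± 153 to 4206 ± 548 CPM). The cytokine genes stood at 0.63 ± 0.15 for Il10 (adjusted p = 0.133) and 1.47 ± 0.43 for Il4 (adjusted p = 0.287), and neither passed.

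With MC903, 11 genes were higher and 24 lower in cKO, with the libraries of both groups apart in all 35 (16.0% of all genes tested and 10% by chance). Here too the split uses the same values as the calls and is no separate support. The clock list went down and was the one list of 26 that also passed with an estimated correlation: of 23, 0 rose, 3 fell and 20 did not pass the test (0 rose and 7 fell adjusted over the list alone). By camera, the clock list had adjusted p = 2.16e-09, and adjusted p = 0.0413 with an estimated correlation. Of 16 type 1 genes, 2 rose, 0 fell and 14 did not pass the test (3 rose and 0 fell adjusted over the list alone). By camera, type 1 genes had adjusted p = 5.84e-04, and adjusted p = 0.201 with an estimated correlation. Among 20 suppressive molecules, 1 rose, 0 fell and 19 did not pass the test (3 rose and 1 fell adjusted over the list alone). By camera, suppressive molecules had adjusted p = 3.61e-04, and adjusted p = 0.201 with an estimated correlation. Interferon-stimulated genes passed upward at a median of 0.43: of 24, 0 rose, 0 fell and 24 did not pass the test (1 rose and 0 fell adjusted over the list alone). By camera, interferon-stimulated genes had adjusted p = 1.76e-06, and adjusted p = 0.201 with an estimated correlation. In the tissue Treg programme of 25, 2 rose, 1 fell and 22 did not pass the test (3 rose and 2 fell adjusted over the list alone). By camera, the tissue Treg programme had adjusted p = 5.84e-04, and adjusted p = 0.201 with an estimated correlation. Type 17 genes passed downward, with Ccr6 and Aqp3 as the called members: of 18, 0 rose, 2 fell and 16 did not pass the test (0 rose and 3 fell adjusted over the list alone). By camera, type 17 genes had adjusted p = 0.00184, and adjusted p = 0.201 with an estimated correlation. Of 18 lymphoid and resting T cell genes, 0 rose, 0 fell and 18 did not pass the test (0 rose and 0 fell adjusted over the list alone). By camera, lymphoid and resting genes had adjusted p = 0.0274, and adjusted p = 0.201 with an estimated correlation. Oxidative phosphorylation and vitamin D response passed upward as well. Of the 32 genes of the former, 0 rose, 0 fell and 32 did not pass the test (0 rose and 0 fell adjusted over the list alone). By camera, oxidative phosphorylation had adjusted p = 0.0116, and adjusted p = 0.784 with an estimated correlation. Of the 9 genes of the latter, 0 rose, 0 fell and 9 did not pass the test (0 rose and 0 fell adjusted over the list alone). By camera, vitamin D response had adjusted p = 0.0144, and adjusted p = 0.201 with an estimated correlation. The other lists outside those of other cells did not pass.

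Some marker lists of other cells passed camera for genotype in MC903 skin, at the preset correlation only. Keratinocyte markers summed to 336 ± 191 CPM in WT and 129.9 ± 108 CPM in cKO, and their list passed downward with Sfn (-1.15 ± 0.17) as the called member of 16 (camera adjusted p = 1.28e-06, adjusted p = 0.201 with an estimated correlation). The libraries of the genotypes overlapped in this sum, at 421, 116 and 469 CPM in WT and 63.2, 71.8 and 255 CPM in cKO. Macrophage, dendritic and Langerhans cell markers summed to 1034 ± 95.0 and 1402 ± 119.7 CPM, and passed upward: of 21, 0 rose, 0 fell and 21 did not pass the test (0 rose and 0 fell adjusted over the list alone). By camera, the macrophage, dendritic and Langerhans list had adjusted p = 1.04e-05, and adjusted p = 0.306 with an estimated correlation. Mast cell, basophil and granulocyte markers summed to 68.4 ± 15.7 and 81.0 ± 13.9 CPM, and passed upward: of 14, 0 rose, 0 fell and 14 did not pass the test (2 rose and 0 fell adjusted over the list alone). By camera, the mast cell, basophil and granulocyte list had adjusted p = 0.00743, and adjusted p = 0.201 with an estimated correlation. CD8, gamma-delta T, NK and innate lymphoid markers summed to 17.5 ± 5.59 and 29.2 ± 4.49 CPM. The number of genes called was 22 without replicate 2 of WT MC903 skin, 23 without replicate 2 and 22 without replicate 3 of cKO MC903 skin. It was 140 by DESeq2 (63 were higher and 77 lower), 104 by limma-voom (50 were higher and 54 lower), and 13 without the 3 libraries richest in fibroblast and endothelial transcripts.

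Averaging the genotype effect over both treatments used 6 cKO and 6 WT skin libraries. Tnfrsf25 (log2 change -2.20 ± 0.12, SE, adjusted p = 3.98e-08), Colq (-4.22 ± 0.26), Ccr6 (-3.87 ± 0.25) and the matrix protein gene Npnt (-2.45 ± 0.35) fell. Gzmb (2.00 ± 0.16), Pde3b (2.25 ± 0.23), the homing receptor gene Gpr15 (1.72 ± 0.19), the lipoxygenase gene Alox8 (2.46 ± 0.45) and the cytotoxic granule gene Nkg7 (1.54 ± 0.17) rose. Gata3 rose by 0.48 ± 0.09, the type 1 regulator gene Tbx21 by 1.08 ± 0.19, the chromatin organiser gene Satb1 by 1.59 ± 0.24 and the aryl hydrocarbon receptor gene Ahr by 0.83 ± 0.15. Foxp3 stood at -0.13 ± 0.17 (adjusted p = 0.84), Il10 at 0.31 ± 0.11 (adjusted p = 0.221) and Il4 at 1.12 ± 0.30 (adjusted p = 0.082), and none of the 3 passed.

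In the averaged effect 120 genes were higher and 117 lower in cKO. Of these, 19 lie within 20 Mb of Rora, Nt5e (-2.11 ± 0.22), Mns1 (-2.43 ± 0.24) and Cox7a2 (-0.68 ± 0.12) among them. Of the 23 clock genes and ROR or REV-ERB targets, 0 rose, 6 fell and 17 did not pass the test (0 rose and 9 fell adjusted over the list alone). By camera, the clock list had adjusted p = 3.63e-09, and adjusted p = 0.0429 with an estimated correlation. They include Arntl (-1.94 ± 0.13), Nr1d1 (-2.03 ± 0.21) and Cry1 (-1.08 ± 0.11). Of 33 TNF receptors and ligands, 5 rose, 2 fell and 26 did not pass the test (8 rose and 3 fell adjusted over the list alone). By camera, TNF receptors and ligands had adjusted p = 0.0298, and adjusted p = 0.336 with an estimated correlation, and those that rose include Cd40lg (1.04 ± 0.12) and Tnfsf8 (1.27 ± 0.20). Among 16 type 1 genes, 2 rose, 1 fell and 13 did not pass the test (5 rose and 1 fell adjusted over the list alone). By camera, type 1 genes had adjusted p = 0.0312, and adjusted p = 0.433 with an estimated correlation. In the type 17 list of 18, 1 rose, 2 fell and 15 did not pass the test (4 rose and 3 fell adjusted over the list alone). By camera, type 17 genes had adjusted p = 0.0312, and adjusted p = 0.433 with an estimated correlation. In the tissue Treg programme of 25, 3 rose, 2 fell and 20 did not pass the test (5 rose and 3 fell adjusted over the list alone). By camera, the tissue Treg programme had adjusted p = 0.00227, and adjusted p = 0.336 with an estimated correlation, and S100a4 was one that fell (-0.63 ± 0.12). The vitamin D response list passed upward, with the phosphatase gene Dusp10 (0.65 ± 0.12) as its called member of 9 (camera adjusted p = 0.0175, adjusted p = 0.182 with an estimated correlation). Interferon-stimulated genes passed upward with 0 of 24 called by edgeR (camera adjusted p = 0.0042, adjusted p = 0.501 with an estimated correlation), and keratinocyte markers passed downward with Sfn (-0.96 ± 0.12) as the called member (camera adjusted p = 0.00227, adjusted p = 0.472 with an estimated correlation). By DESeq2, 462 genes passed in the whole comparison, and edgeR called 107 without the 3 libraries richest in fibroblast and endothelial transcripts.

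**Figure D3:**
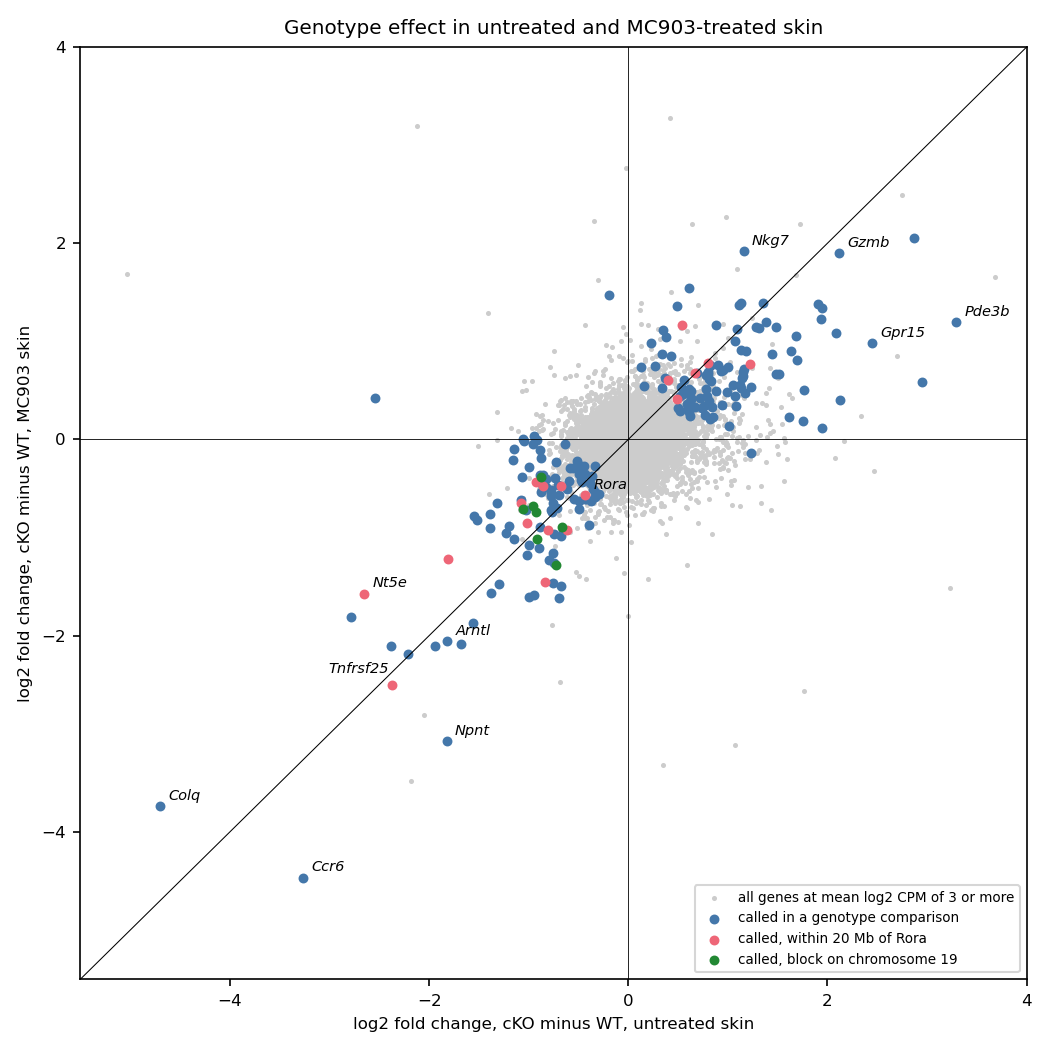
Log2 fold change of cKO over WT in untreated skin (horizontal axis) and in MC903 skin (vertical axis) for genes at a mean log2 CPM of 3 or more, with genes called in a genotype comparison coloured and the line of equal change drawn. Ccr6, Colq, Tnfrsf25 and Arntl lie low on both axes, and Gzmb lies high on both.

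Whether MC903 changed the effect of genotype was tested as an interaction of genotype and treatment. Tnfrsf25 had an interaction of 0.03 ± 0.22 on the log2 scale and Rora one of -0.13 ± 0.21 (SE, adjusted p = 1 and 0.961). Gpr15 stood at -1.47 ± 0.37 (adjusted p = 0.668), Cry1 at -0.82 ± 0.22 (0.719) and Il10 at 0.65 ± 0.22 (0.866). By edgeR 0 genes passed, with 765 at an unadjusted p under 0.05, while DESeq2 called 17. Without replicate 1 or replicate 2 of WT untreated skin the edgeR count was 1. Camera passed 7 of the 26 lists at the preset correlation and 0 with an estimated one (adjusted p = 0.186 or more).

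The genotype effects in untreated and in MC903 skin correlated across genes at r = 0.110, and at r = 0.321 for genes at a mean log2 CPM of 3 or more. Of the 109 genes called in untreated skin, 103 had the same sign in MC903 skin, and 20 were called in both, each with the same sign, where independent lists would share 0.141 in the same direction. Those called in both include Colq, Ccr6, Tnfrsf25, Arntl, Aqp3 and Gzmb. Dapk2, Mns1, Leo1, Suv420h1 and Ndufv1 were also called in both. They lie in the 2 chromosome segments described below, where a DNA difference between the mouse lines is left open.

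In WT mice, MC903 skin was compared with untreated skin to see how skin Tregs change in inflamed skin. Cxcr5 (log2 change 4.20 ± 0.48, SE, n = 3 per group, adjusted p = 9.05e-05), the lymphocyte GTPase genes Gimap7 (3.91 ± 0.50) and Gimap4 (3.01 ± 0.33), and Lef1 (1.13 ± 0.16) rose. Gpr15 (3.56 ± 0.29) and the inhibitory receptor gene Pdcd1 (1.74 ± 0.21) rose as well. Ifng (-3.50 ± 0.50), Tbx21 (-3.13 ± 0.29) and Tnf (-2.09 ± 0.35) fell. So did Il10 (-1.45 ± 0.16, from 552 ± 5.94 to 202 ± 25.6 CPM, SD), Areg (-1.29 ± 0.21), the skin homing receptor genes Ccr10 (-3.06 ± 0.49) and Cxcr6 (-2.22 ± 0.22), and Rora (-0.82 ± 0.15).

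With MC903, 683 genes rose and 738 fell in WT Tregs. The immediate early and heat shock list passed downward: of 25, 0 rose, 18 fell and 7 did not pass the test (0 rose and 21 fell adjusted over the list alone). By camera, immediate early genes had adjusted p = 5.71e-27, and adjusted p = 0.00693 with an estimated correlation, and Dusp1 was at -1.99 ± 0.20. Of 18 lymphoid and resting T cell genes, 9 rose, 3 fell and 6 did not pass the test (10 rose and 4 fell adjusted over the list alone). By camera, lymphoid and resting genes had adjusted p = 4.05e-05, and adjusted p = 0.0264 with an estimated correlation. Among 20 NF-kappa-B targets, 0 rose, 7 fell and 13 did not pass the test (0 rose and 11 fell adjusted over the list alone). By camera, NF-kappa-B targets had adjusted p = 4.05e-05, and adjusted p = 0.0378 with an estimated correlation. The clock list went down, with Ciart at -1.17 ± 0.20 and Nr1d1 at -2.23 ± 0.30: of 23, 0 rose, 8 fell and 15 did not pass the test (0 rose and 8 fell adjusted over the list alone). By camera, the clock list had adjusted p = 2.47e-05, and adjusted p = 0.0545 with an estimated correlation. In the tissue Treg programme of 25, 2 rose, 6 fell and 17 did not pass the test (3 rose and 8 fell adjusted over the list alone). By camera, the tissue Treg programme had adjusted p = 9.60e-05, and adjusted p = 0.162 with an estimated correlation. Type 1 genes gave this count of 16: 2 rose, 6 fell and 8 did not pass the test (2 rose and 6 fell adjusted over the list alone). By camera, type 1 genes had adjusted p = 0.00233, and adjusted p = 0.213 with an estimated correlation. Oxidative phosphorylation passed upward at a median of 0.21: of 32, 1 rose, 0 fell and 31 did not pass the test (0 rose and 0 fell adjusted over the list alone). By camera, oxidative phosphorylation had adjusted p = 0.0247, and adjusted p = 0.905 with an estimated correlation. The vitamin D response list did not pass: of 9, 0 rose, 1 fell and 8 did not pass the test (1 rose and 2 fell adjusted over the list alone). By camera, vitamin D response had adjusted p = 0.486, and adjusted p = 0.905 with an estimated correlation. Its median (0.07) and mean (0.63) were positive while the test pointed down. Macrophage, dendritic and Langerhans cell markers summed to 1528 ± 450.4 CPM in untreated and 1034 ± 95.0 CPM in MC903 skin, and keratinocyte markers to 498 ± 186 and 336 ± 191 CPM. The number of genes called was 767 without replicate 1 and 833 without replicate 3 of WT MC903 skin, 946 without replicate 2 of WT untreated skin, and 514 with only these 6 libraries in the fit. It was 758 without the 3 libraries richest in fibroblast and endothelial transcripts.

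In cKO mice the same treatment was compared to see whether cKO Tregs respond. Cxcr5 (log2 change 5.43 ± 0.50, SE, n = 3 per group, adjusted p = 1.44e-05), Gimap1 (2.16 ± 0.18), Gpr15 (2.09 ± 0.26) and Pdcd1 (2.24 ± 0.21) rose. The motor protein gene Myo6 (3.81 ± 0.28), the adenosine kinase gene Adk (1.93 ± 0.16), Lrrc32, which displays latent TGF-beta (2.13 ± 0.34), and Nt5e, which lies within 20 Mb of Rora (1.82 ± 0.31), also rose. Ifng (-2.43 ± 0.47), Tbx21 (-2.20 ± 0.28), the small heat shock protein gene Hspb1 (-2.73 ± 0.27), the transcriptional regulator gene Id2 (-1.50 ± 0.16), Areg (-1.34 ± 0.21), Il10 (-0.81 ± 0.15) and Rora (-0.95 ± 0.15) fell.

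In cKO Tregs 809 genes rose and 720 fell with MC903. Of 25 immediate early and heat shock genes, 0 rose, 18 fell and 7 did not pass the test (0 rose and 19 fell adjusted over the list alone). By camera, immediate early genes had adjusted p = 5.11e-25, and adjusted p = 0.00675 with an estimated correlation. In the lymphoid and resting list of 18, 8 rose, 1 fell and 9 did not pass the test (10 rose and 2 fell adjusted over the list alone). By camera, lymphoid and resting genes had adjusted p = 7.70e-07, and adjusted p = 0.00675 with an estimated correlation. Among 20 NF-kappa-B targets, 0 rose, 8 fell and 12 did not pass the test (0 rose and 8 fell adjusted over the list alone). By camera, NF-kappa-B targets had adjusted p = 7.70e-07, and adjusted p = 0.0169 with an estimated correlation. Clock genes and ROR or REV-ERB targets, led by Hlf (-3.64 ± 0.47) and Nr1d1 (-2.39 ± 0.31), passed downward: of 23, 0 rose, 10 fell and 13 did not pass the test (0 rose and 10 fell adjusted over the list alone). By camera, the clock list had adjusted p = 2.98e-07, and adjusted p = 0.0299 with an estimated correlation. Oxidative phosphorylation genes passed upward, among them Ndufa1 (0.75 ± 0.15) and Atp5j (0.73 ± 0.15). Of 32, 18 rose, 0 fell and 14 did not pass the test (24 rose and 0 fell adjusted over the list alone). By camera, oxidative phosphorylation had adjusted p = 2.02e-12, and adjusted p = 0.347 with an estimated correlation. Treg identity genes such as Folr4 (2.33 ± 0.27) passed upward: of 18, 6 rose, 0 fell and 12 did not pass the test (6 rose and 0 fell adjusted over the list alone). By camera, Treg identity had adjusted p = 5.56e-04, and adjusted p = 0.0502 with an estimated correlation. In the tissue Treg programme of 25, 1 rose, 9 fell and 15 did not pass the test (2 rose and 9 fell adjusted over the list alone). By camera, the tissue Treg programme had adjusted p = 7.35e-04, and adjusted p = 0.202 with an estimated correlation. TCR activation genes passed downward: of 20, 2 rose, 6 fell and 12 did not pass the test (2 rose and 7 fell adjusted over the list alone). By camera, TCR activation genes had adjusted p = 0.0198, and adjusted p = 0.367 with an estimated correlation. Of 24 cholesterol synthesis genes, 1 rose, 3 fell and 20 did not pass the test (1 rose and 7 fell adjusted over the list alone). By camera, cholesterol synthesis had adjusted p = 0.031, and adjusted p = 0.447 with an estimated correlation.

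Keratinocyte markers summed to 372 ± 112 CPM in untreated and 129.9 ± 108 CPM in MC903-treated cKO skin, and passed downward (camera adjusted p = 0.00275, adjusted p = 0.447 with an estimated correlation), with Sfn at -2.04 ± 0.17. Mast cell, basophil and granulocyte markers summed to 39.1 ± 5.75 and 81.0 ± 13.9 CPM, and passed upward with 2 of 14 called (camera adjusted p = 5.38e-04, adjusted p = 0.164 with an estimated correlation). The histamine-producing enzyme gene Hdc was one of them (1.60 ± 0.25). The number of genes called was 662 without replicate 2 and 662 without replicate 3 of cKO untreated skin. It was 980, 645 and 802 without replicates 1, 2 and 3 of cKO MC903 skin in turn, and 2642 by limma-voom.

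The MC903 effects in WT and in cKO Tregs correlated across genes at r = 0.397, and at r = 0.727 for genes at a mean log2 CPM of 3 or more. In both genotypes 757 genes were called, 756 of them with the same sign, where independent lists would share 79.8 in the same direction. Cxcr5, Pdcd1, Ifng, Tbx21, Il10 and Areg are among them.

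Of the type 2 cytokine genes, Il13 was higher in skin than in LN by 6.31 ± 0.97 and Il4 by 1.15 ± 0.43 (adjusted p = 0.0315). The Il4 call ended without replicate 2 of WT skin or any 1 LN library (adjusted p = 0.0677 to 0.162). Il5 also passed as higher in skin, at 1.23, 4.42 and 0 CPM in the WT skin libraries and 0 in each LN library. The Il5 call ended with limma-voom (adjusted p = 0.184) and, in a run chosen after seeing the data, without replicate 2 of WT skin and replicate 3 of LN together (adjusted p = 0.0689). In the averaged genotype effect Il5 stood at 0.03 ± 1.01, Il13 at 0.35 ± 0.51, Areg at 0.13 ± 0.15 and Il1rl1 at 0.16 ± 0.10, with adjusted p of 0.604 or more. With MC903, Il13 stood at -1.75 ± 0.74 in WT (adjusted p = 0.148, from 3.03 ± 1.02 to 0.900 ± 0.943 CPM, SD) and -2.23 ± 0.75 in cKO (adjusted p = 0.0667, from 4.59 ± 0.361 to 0.974 ± 0.0256 CPM), and neither passed. In WT it passed with limma-voom (adjusted p = 0.0354) and without replicate 2 of MC903 skin (0.0311). In cKO it passed with DESeq2 (0.0153), limma-voom (0.00453) and the compared groups alone (0.0129). Il4 and Il5 did not pass with MC903 in either genotype (adjusted p = 0.322 to 0.994).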

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

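The test of these results, the interaction of genotype and MC903 over the gene lists, was planned before the data were examined. In each of the 7 lists named here the genotype effect differed between untreated and MC903 skin by camera at the preset correlation, and none passed with an estimated correlation. The 18 Treg identity genes shifted up (camera adjusted p = 5.51e-04, adjusted p = 0.186 with an estimated correlation, median log2 interaction 0.35). Suppressive molecules, 20 genes, shifted up (camera adjusted p = 0.00351, adjusted p = 0.658 with an estimated correlation, median log2 interaction 0.28). Interferon-stimulated genes, 24 of them, shifted up (camera adjusted p = 0.00351, adjusted p = 0.658 with an estimated correlation, median log2 interaction 0.47). Oxidative phosphorylation genes, 32 in number, shifted up (camera adjusted p = 7.41e-09, adjusted p = 0.658 with an estimated correlation, median log2 interaction 0.37). Keratinocyte markers, 16 genes, shifted down (camera adjusted p = 0.00232, adjusted p = 0.658 with an estimated correlation, median log2 interaction -1.31), with summed levels of 498 ± 186 and 372 ± 112 CPM in untreated WT and cKO skin and 336 ± 191 and 129.9 ± 108 CPM (SD, n = 3) with MC903. Macrophage, dendritic and Langerhans cell markers, 21 genes, shifted up (camera adjusted p = 1.01e-04, adjusted p = 0.658 with an estimated correlation, median log2 interaction 1.14), with 1528 ± 450.4 and 1778 ± 693 CPM in untreated WT and cKO skin and 1034 ± 95.0 and 1402 ± 119.7 CPM with MC903. Mast cell, basophil and granulocyte markers, 14 genes, shifted up (camera adjusted p = 0.00351, adjusted p = 0.605 with an estimated correlation, median log2 interaction 2.99), with 57.6 ± 9.56 and 39.1 ± 5.75 CPM in untreated WT and cKO skin and 68.4 ± 15.7 and 81.0 ± 13.9 CPM with MC903. In the last 2 lists some members lay near the floor. Cpa3 had 0 counts in untreated cKO skin (interaction 8.91) and C1qa had 12 (7.57). Medians over such members can be larger than the change of the summed levels. By edgeR 0 single genes passed the interaction test, with 765 at an unadjusted p under 0.05 and 17 called by DESeq2. No group has 4 libraries, so no library was tested for standing apart from its group.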

How the results depend on the processing

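The runs without the 3 libraries richest in fibroblast and endothelial transcripts, without replicate 3 of LN and replicate 2 of WT untreated skin together, and without the genes of 2 chromosome segments were chosen after seeing the data, and the others before. Under every alternative run, no named gene that passed changed sign, and the skin against LN count stayed within 1.5 times of 7824. DESeq2 called 323 genes for genotype in untreated skin, 140 in MC903 skin, 462 in the averaged effect and 17 for the interaction. Limma-voom called 104 for genotype in MC903 skin and 2642 for MC903 in cKO. With only its own groups in the fit, MC903 in WT gave 514. For these counts the cause was not tested. With 1 library left out in turn, fewer samples remain, and the counts ran over 60 to 133 for genotype in untreated skin, 22 to 31 in MC903 skin, 767 to 1410 for MC903 in WT, 645 to 1895 in cKO and 0 to 1 for the interaction. Without the 3 libraries richest in fibroblast and endothelial transcripts the counts were 54, 13, 758 and 1 for genotype in untreated skin, genotype in MC903 skin, MC903 in WT and the interaction, and 107 for the averaged effect. Without replicate 3 of LN and replicate 2 of WT untreated skin the interaction gave 1. At a mean log2 CPM of 3 or more, where fewer genes are counted, the correlation across genes rose to 0.321 for genotype and 0.727 for MC903. With an estimated correlation, camera passed 7 lists for skin against LN, 0 and 1 for genotype in untreated and MC903 skin, 3 and 4 for MC903 in WT and cKO, 0 for the interaction and 1 for the averaged effect. Leaving out 1 library gave 2 to 5 lists for genotype in untreated skin and 3 to 13 for the averaged effect. Of the 480 values of named genes, DESeq2 ended the call of 2 and added 28, limma-voom ended 30 and added 12, the compared groups alone ended 37 and added 3, and the replicate block ended 16 and added 3. Without the 3 libraries richest in fibroblast and endothelial transcripts 55 ended. Without replicate 3 of LN and replicate 2 of WT untreated skin 29 ended and 3 were added. The runs that left out 1 library ended 294 and added 14 in all.

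Replicate numbers shared by libraries of different groups were not taken as pairs. Of 30 same-number pairs, 3 correlated above 0.1 after group means were removed, over -0.277 to 0.223. With the replicate block the fits called 7550, 90, 34, 1232, 1325, 0 and 200 genes for skin against LN, genotype in untreated and MC903 skin, MC903 in WT and cKO, the interaction and the averaged effect, and 4 lists passed for genotype in untreated skin.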

Other observations

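The tests of gene families, of the chromosome segments, of the clock genes and of other splits of the libraries were specified only after the results were seen. Gene families taken by symbol, 20 of them, were tested with camera. Some share members with the fixed lists, such as Gzmb and Dusp1, and are not independent of them. The GIMAP family, GTPases of lymphocyte survival, was low in skin Tregs and higher in MC903-treated ears than in untreated back skin with ears. Treatment and site cannot be told apart there. In skin against LN 0 of 8 rose and 8 fell at a median of -3.22, camera adjusted p = 5.67e-09, adjusted p = 0.177 with an estimated correlation. With MC903 in WT 8 of 8 rose and 0 fell at a median of 2.32, camera adjusted p = 4.12e-27, adjusted p = 0.0271 with an estimated correlation. In cKO 8 of 8 rose and 0 fell at a median of 2.64, camera adjusted p = 2.10e-32, adjusted p = 0.0143 with an estimated correlation, with Gimap1 at 2.16 ± 0.18 (SE, n = 3 per group).

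Of Schlafen genes, interferon-inducible regulators of lymphocyte growth, 0 of 8 rose and 5 fell at a median of -1.60, camera adjusted p = 2.18e-04, adjusted p = 0.0204 with an estimated correlation in skin against LN. In the genotype effect averaged over treatments 3 of 8 rose and 0 fell at a median of 0.31, camera adjusted p = 1.22e-04, adjusted p = 0.0179 with an estimated correlation. By treatment the Schlafen genes had adjusted p = 0.00736 and 0.129 with an estimated correlation in untreated skin, and 3.42e-04 and 0.0235 in MC903 skin, with 1 and 0 of 8 called. Among granzymes, with Gzmb as the called member, 1 of 5 rose and 0 fell at a median of 1.25, camera adjusted p = 2.81e-04, adjusted p = 0.0395 with an estimated correlation in the averaged effect. Their adjusted p was 0.0537 and 0.436 with an estimated correlation in untreated skin, where they did not pass, and 1.43e-04 and 0.0235 in MC903 skin. Marker sums of CD8, gamma-delta T, NK and innate lymphoid cells were also higher in cKO, 33.3 ± 3.80 against 18.8 ± 0.721 CPM (SD, n = 3) in untreated skin and 29.2 ± 4.49 against 17.5 ± 5.59 CPM in MC903 skin. In untreated skin Cd8b1 stood at 17.1 ± 5.31 CPM in cKO and 9.65 ± 0.712 CPM in WT. Prf1, which is also in the list of suppressive molecules, stood at 4.30 ± 1.92 and 1.92 ± 0.237 CPM. Cd8a lay near the floor and was not higher, at 0.104 ± 0.180 and 0.587 ± 0.926 CPM. Whether more such cells were present was not tested. Among dual specificity phosphatases, which switch off MAP kinases, 12 of 19 rose and 2 fell at a median of 2.17, camera adjusted p = 1.23e-04, adjusted p = 0.0204 with an estimated correlation in skin against LN.

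Genes called in the averaged genotype effect were dense around Rora. Within 20 Mb of it on chromosome 9, 19 of 255 tested genes were called (8 higher and 11 lower), a share of 7.45% against 1.62% elsewhere (permutation p = 0.0001, the smallest that 10000 permutations of the called genes can give). They include Prss35 (4.71 ± 0.96), Dapk2 (4.10 ± 0.51), Mns1 (-2.43 ± 0.24) and Nt5e (-2.11 ± 0.22) on the log2 scale (SE). Prss35 lies near the floor, at a mean log2 CPM of -0.42, and Dapk2 is low at 2.00. By edgeR, Prss35 did not pass in untreated skin (adjusted p = 0.25) or in MC903 skin (adjusted p = 0.178). The tables argue against a window rich in calls of any kind, since its share for MC903 in WT was 1.05 times that elsewhere, and against an effect on near neighbours alone, since 17 called genes lie beyond 2 Mb. A chromosome segment of another strain carried along with the floxed allele remains a candidate explanation, as the share was 4.60 times that elsewhere with genes moving both ways, and changes of Nt5e or Mns1 may therefore not need Rora.

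In a block of 13 neighbouring genes on chromosome 19, 7 were called, all lower in cKO, among them Suv420h1, Chka, Tcirg1, Ndufs8, Ndufv1 and Gstp1. Their median averaged log2 change was -0.83, each at -0.63 or lower, while the 12 expressed genes that flank the block had a median of -0.01. The block was found by its calls, around the window of 12 neighbouring genes with the most. It ends at its first and last called gene, so the contrast between called members and nearest flanks follows in part from that choice. The other 6 did not pass: Unc93b1 and Nudt8 stood at -0.52 and -0.50, and 4 lie at a mean log2 CPM under 3, of which Aldh3b1 stood at 0.24. A copy-number difference between the mouse lines and regulation by Rora cannot be told apart. The 2 expressed members that were not called are too few for a test (median -0.51), the called members were also low in MC903 skin (median -0.74), and the DNA was not measured.

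In the clock list, 6 of 23 genes were called lower in cKO. Arntl and Nr1d1 stood at 0.284 and 0.260 of WT in untreated skin and at 0.241 and 0.232 in MC903 skin. Fewer keratinocyte transcripts were examined as a cause. Keratinocyte sums were 0.748 and 0.387 of WT in untreated and MC903 skin. The lower sum in untreated skin was not shared by every marker. There Sfn stood at 257 ± 45.4 CPM in WT and 152 ± 20.8 CPM in cKO (SD), and Krt14 at 52.2 ± 43.5 and 78.4 ± 50.6 CPM. Transcripts that move with the keratinocyte markers would follow these sums within groups with a slope near 1 on the log2 scale. The slopes were 0.01 ± 0.11 for Arntl, 0.16 ± 0.19 for Nr1d1 and 0.00 ± 0.08 for the mean of Cry1, Nr1d2, Ciart and Hlf (SE, 12 skin libraries). That argues against transcripts that move with the sum. Not every listed marker does: in WT MC903 skin the sums were 421, 116 and 469 CPM and Sfn stood at 74.6, 71.0 and 101.1. The slopes therefore do not decide on keratinocyte transcripts that vary as Sfn does. For Arntl the tables argue against B cells, against CD8, gamma-delta T, NK and innate lymphoid cells and against erythroid cells and platelets. None of these marker sums exceeded 23.5 CPM in a WT skin library, while Arntl lost 80.7 and 79.5 CPM. Fibroblast and endothelial sums were 0.896 and 1.29 of WT in untreated and MC903 skin. Those of macrophages, dendritic and Langerhans cells were 1.16 and 1.36, and those of mast cells, basophils and granulocytes 0.678 and 1.18. In MC903 skin the lowest cKO library held 0.519, 1.14 and 0.804 of the highest WT library. Arntl and Nr1d1 stood lower there, as did Cry1, Nr1d2, Ciart and Hlf at a median of 0.441 of WT. This argues against fewer transcripts of these cells as the whole cause in MC903 skin, as far as the sums stand for them. In untreated skin these cells cannot be told apart from a change in Tregs. Of 221 named genes outside the marker lists 13, 20 and 8 followed these 3 lists in turn within groups at an unadjusted p under 0.05, where chance gives 11.1, so an adjustment for them tests little. The keratinocyte list was followed by 20 as well. Cells without a list stay open. A different time of day at collection also stays open, because the output genes Per1, Per2, Per3, Dbp and Tef had a median averaged log2 change of -0.45 and the labels give no time. Loss of a direct action of ROR-alpha on Arntl and Nr1d1 may be a further explanation, which these tables did not test.

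Other splits of the same libraries into groups of 3 were fitted. For each comparison of 3 against 3 there are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave the most genes. The real counts and the highest of the other splits were 7824 and 0 for skin against LN, 109 and 4 for genotype in untreated skin, 35 and 1 in MC903 skin, 1421 and 0 for MC903 in WT, and 1529 and 1 in cKO. For the averaged genotype effect, 100 of 200 possible splits were fitted, and 1 of the 100, the real one, gave as many as 237 genes. The highest other gave 92, so a split by chance is an unlikely source of this count but is not excluded. For the interaction the real count was 0 by edgeR (765 at an unadjusted p under 0.05, 17 by DESeq2), a count that any split matches, so the splits do not test it. The highest other split gave 92 and the next gave 7. The split at 92 kept the genotypes of untreated skin and exchanged 2 labels of each genotype in MC903 skin. The highest other split of the averaged effect divided the libraries in the same way, with the MC903 labels mirrored. Both counts of 92 thus come from the same contrast, and its source was not tested.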
